A study of Mus musculus with 8 samples.

How the data were processed

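Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on mouse embryonic fibroblasts (MEF), connective tissue cells taken from embryos, in wild-type (WT) cells and in cells labelled as KAP1 knockout (KO). Per the labels' protocols, chromatin was fixed for 10 min in 1% formaldehyde, sonicated to fragments of 200 to 400 bp and precipitated with antibodies against KAP1, H3K9me3 or H4K20me3. The 8 samples comprised 5 ChIP libraries and 3 input libraries without antibody, each the only library of its group. Peak lists of the 5 ChIP libraries were analysed. The inputs were not analysed here.

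The deposited lists hold 1 line per peak, with the chromosome, start, end, a peak name and a score. Per the submitters' processing notes, CASAVA 1.82, Bowtie2 2.2.1 and MACS 1.4 were used, and the genome build was mm9. MACS calls regions in which reads exceed a local background. The parameters of the calls and the control of each histone call are not given in the sources used here. Per the file headers, the KAP1 list compares 1 WT KAP1 library with 1 WT MEF library. The deposited score of a peak is the authors' own value and is read here as a MACS score. Its lowest value was 50 in all 5 lists after rounding, as for -10 times log10 of a p-value of 1e-05, but this reading rests on the values and is not stated in the sources used here. A score of this kind grows with the depth of a library and with the width of the peak, so scores were used to rank and filter peaks within a list. Ratios of scores between lists appear in the closing section only, uncentred, to be compared between chromosomes and not read as amounts. Peaks of 1 list did not overlap each other. The files give no read counts, so the depth behind each peak is unknown, and a library of lower depth gives fewer peaks at the same threshold. An absent peak means that no peak was called, not that the mark was absent.

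Positions were used as deposited and are printed counting from 1. A peak was counted as kept, shared or overlapping when at least 1 bp of it lay in a peak of the other list, and a WT peak without such a KO peak is called lost. Overlaps were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. All 40 combinations of list pair and overlap rule compared with bedtools 2.31.1 gave the same call for every peak. Shares are given with exact Clopper-Pearson 95% intervals from scipy 1.17.1. These cover counting error over peaks alone. With 1 library per group there was no replicate error, no test between genotypes and no p-value, and differences have no replicate check.

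Chance overlap was measured with 1000 random placements of the peaks, each uniform within the stretch of its chromosome from the lowest to the highest peak of any list. The share of kept peaks at KAP1 sites was set against 10000 random sets of WT peaks of the same size, matched on the decile of score. On simulated data, lists made from the WT H3K9me3 and H4K20me3 peaks with a known share kept returned that share and the known number of new peaks without error. This checks the counting alone, because kept peaks were made to overlap WT peaks and new peaks to lie clear of them. In 100 simulated runs with 200 H4K20me3 peaks per set, the set's share lay inside the middle 95% of matched sets in 97 runs without an effect. It lay below them in all 100 runs in which the share kept was cut by 50%. Keeping was drawn independently for each peak, so clustering of peaks was not covered.

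The alternatives were an overlap of at least 50% of the peak, a distance of up to 1 kb, a score of at least 100 in every list, equal numbers of highest-scoring peaks for both genotypes of a mark, peaks within 5 kb merged, and chromosomes 1 to 19 and X alone. Placement by circular shift and matching on length were also tried. These choices, the groups and the rule for named regions were fixed before the data were examined. Classes of H4K20me3 peaks by the WT H3K9me3 list alone, counts per chromosome and the plots were chosen after the data had been seen. The named regions are the highest-scoring lost, kept and new peaks of each mark and the highest-scoring KAP1 peaks on chromosomes 1 to 19, X and Y, up to 5 of each, and the windows of 1 Mb with most WT H3K9me3 peaks and with the largest loss of peaks. No annotation of build mm9 was used here, so regions are given by position, and the planned comparisons of gene lists and of promoters, exons and introns were not run. No library measured KAP1 in the KO cells, so the knockout itself was not checked.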

Results

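Peaks of KAP1, H3K9me3 and H4K20me3 were mapped in MEF. KAP1 (also called TRIM28) is a corepressor that KRAB zinc finger proteins recruit to DNA, and H3K9me3 and H4K20me3 are histone marks of heterochromatin. KAP1 was profiled in WT cells, and both marks were profiled in WT and KAP1 KO cells, with 1 library for each. The series' title states its subject as the role of KAP1 in restoring heterochromatin after DNA replication. The WT lists held 14596 H3K9me3 peaks and 11295 H4K20me3 peaks, and the KO lists 3176 and 8920. The KAP1 list held 372 peaks. Median peak lengths were 459 bp for H3K9me3 in WT and 457 bp in KO, 766 bp for H4K20me3 in WT and 794 bp in KO, and 491 bp for KAP1.

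The first comparison asked how H3K9me3 differed between WT and KO cells. Of the 14596 WT peaks, 452 had a peak at the same place in the KO list, a share of 3.10% (95% interval 2.82 to 3.39%). The other 14144 were lost. Covered length was 8.87 Mb in WT, with a mean peak length of 608 bp, and 2.29 Mb in KO, with a mean of 722 bp, a KO to WT ratio of 0.259, or 0.628 for equal numbers of highest-scoring peaks. Of the 3176 KO peaks, 2745 (86.4%, interval 85.2 to 87.6%) lay where no WT peak was called. Their median score was 61.0, near the lowest score of the list. The share of KO peaks found in WT was 3.46% in the lowest decile of KO score and 48.9% in the highest. The overlap still exceeded chance, since 0.244% of WT peaks met a KO peak under random placement, and at most 0.397% in any of 1000 placements. The share kept was 5.95% among equal numbers of highest-scoring peaks and 6.59% with a distance of up to 10 kb.

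The lost H3K9me3 peaks included those with the highest scores. The highest-scoring one spanned 11407 bp on chromosome 2, from 157379229 to 157390635, with a score of 3100. The next 4 lay on chromosome 5 (144012813 to 144018417, score 2905), chromosome 3 (98228258 to 98234511, score 2775), chromosome 8 (71749316 to 71755932, score 2478) and chromosome 4 (145415018 to 145422677, score 2301). All 5 overlapped a WT H4K20me3 peak, and those on chromosomes 2, 5 and 3 also overlapped a KAP1 peak. The one on chromosome 4 directly adjoins a kept H3K9me3 peak (145422680 to 145430752), so a single stretch can hold both a lost and a kept peak. Among the 500 highest-scoring WT peaks, 60 were kept (12.0%, interval 9.28 to 15.2%), and among the 500 highest-scoring KO peaks 209 were found in WT (41.8%, interval 37.4 to 46.3%). The share kept was 1.64% in the lowest decile of score and 7.81% in the highest, and 1.37% in the shortest decile of length and 12.1% in the longest.

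**Figure D1:**
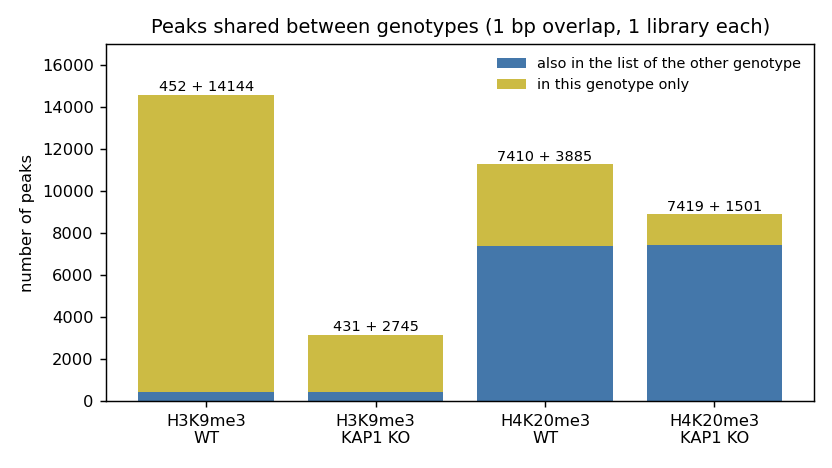
Number of peaks (vertical axis) in the WT and KO lists of each mark, 1 library each, split into peaks that overlap a peak of the other genotype by at least 1 bp (blue) and peaks of 1 genotype only (yellow). For H3K9me3, 452 of 14596 WT peaks were shared, and for H4K20me3 7410 of 11295.

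A minority of strong H3K9me3 regions were called in both genotypes. The region with the highest score, on chromosome 10 from 7230779 to 7235418, had a WT score of 3100. The next lay on chromosome 12 (20232477 to 20240604, WT score 2537), chromosome 4 (145422680 to 145430752, WT score 2379), chromosome 10 (7229218 to 7230612, WT score 2097) and chromosome 1 (188553451 to 188556334, WT score 1926). In the same order from the first region, the KO scores were 3065, 335, 196, 1284 and 1732, so a kept peak need not have a high KO score. Both regions on chromosome 10 lie close together, and the chromosome 4 region adjoins the lost peak named above. The highest-scoring KO peak without a WT peak lay on chromosome 4 (118219582 to 118221548, score 1165). The next lay on chromosome 18 (5788960 to 5790550), with a score of 415.

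H3K9me3 peaks and their losses were spread over many windows of 1 Mb. The 3 windows with most WT peaks were also those with the largest losses, which follows largely from counting loss as the drop in peak number. On chromosome 4, the window from 146 to 147 Mb held 280 WT and 7 KO peaks, and the window from 145 to 146 Mb held 232 and 5. The window from 81 to 82 Mb on chromosome 10 held 141 WT peaks and 1 KO peak. Of the 2357 windows of 1 Mb with an H3K9me3 peak in either genotype, 2012 held fewer peaks in KO, 231 held more and 114 held equal numbers. Fewer H3K9me3 peaks were called in KO on each of the 20 chromosomes 1 to 19 and X. The KO to WT ratio of peak numbers was lowest on chromosome 13, at 0.0366, and highest on chromosome 18, at 0.425. The share of WT peaks kept ranged from 1.44% on chromosome 13 to 9.74% on chromosome X.

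**Figure D2:**
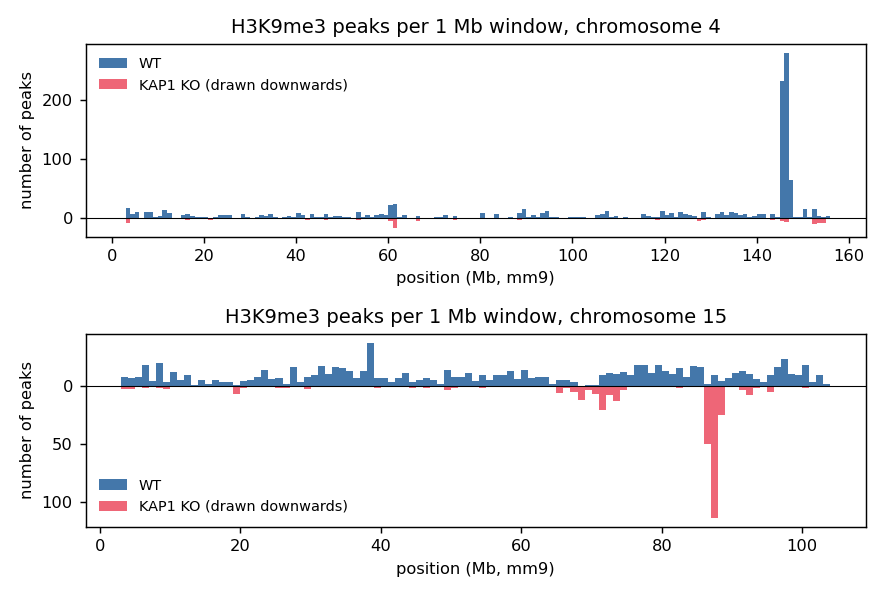
H3K9me3 peaks per 1 Mb window (vertical axis) along chromosomes 4 and 15 (position in Mb, mm9), WT upwards in blue and KAP1 KO downwards in red, 1 library each. The WT peaks at 145 to 147 Mb of chromosome 4 had few KO counterparts, and chromosome 15 held 114 KO and 9 WT peaks at 87 to 88 Mb.

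The second comparison asked the same of H4K20me3. Most H4K20me3 peaks were found in both genotypes. Of the 11295 WT peaks, 7410 were kept in KO (65.6%, interval 64.7 to 66.5%), while random placement gave 0.674%. Of the 8920 KO peaks, 1501 (16.8%, interval 16.1 to 17.6%) lay where no WT peak was called. Covered length was 9.81 Mb in WT and 7.91 Mb in KO, a ratio of 0.806, with mean peak lengths of 868 and 887 bp. Among the 500 peaks with the highest scores, 457 WT peaks were kept and 495 KO peaks were found in WT.

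The strongest H4K20me3 peaks that were lost lay mostly on H3K9me3 peaks. The highest-scoring, on chromosome 10 from 79197894 to 79205637, had a score of 3185 and overlapped an H3K9me3 peak and a KAP1 peak. The next 4 lay on chromosome 2 (157379463 to 157386074, score 1834), chromosome 5 (23212248 to 23217616, score 1784), chromosome 8 (73118030 to 73122904, score 1482) and chromosome 17 (71078868 to 71080863, score 1331). Each overlapped a WT H3K9me3 peak. The kept peaks on chromosome 8 (125625897 to 125628072), chromosome 2 (32816964 to 32819043) and chromosome 3 (85945111 to 85946821) overlapped no H3K9me3 peak. Their WT scores were 3100, 3041 and 2959. The other 2 kept peaks among the 5 with the highest scores, on chromosome 12 (114013611 to 114017592 and 114019667 to 114023443), did overlap WT H3K9me3 peaks, both with a WT score of 3100. Their KO peaks scored 117 and 255, while those on chromosomes 8, 2 and 3 scored 3100, 3173 and 2166. The largest losses per window were from 23 to 2 peaks at 75 to 76 Mb of chromosome 17, from 27 to 6 at 149 to 150 Mb of chromosome 6 and from 21 to 1 at 27 to 28 Mb of chromosome 13.

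The third comparison asked whether both marks were lost at the same places. H4K20me3 peaks that lay on H3K9me3 peaks in WT cells were seldom called in KO cells, and those elsewhere mostly were. Of the 1197 WT H4K20me3 peaks on a WT H3K9me3 peak, 90 were kept (7.52%, interval 6.09 to 9.16%). Of the 10098 others, 7320 were kept (72.5%, interval 71.6 to 73.4%). By number, more of the lost H4K20me3 peaks lay off WT H3K9me3 peaks (2778) than on them (1107). These classes use the WT H3K9me3 list alone, a comparison added after the data were seen. Random sets of WT H4K20me3 peaks matched on decile of score kept 58.5% on average, and no set of 10000 kept less than 53.6%. They were drawn from all WT H4K20me3 peaks, these 1197 included. Where the H3K9me3 peak was lost, 48 of 1116 H4K20me3 peaks were kept (4.30%, interval 3.19 to 5.66%), a share of 7.15% with a distance of up to 1 kb and 12.2% with peaks within 5 kb merged. Where the H3K9me3 peak was kept, 42 of 81 were (51.9%, interval 40.5 to 63.1%). In the highest decile of H4K20me3 score, 22.9% of the peaks on H3K9me3 were kept, and 98.9% of the others. With peaks within 5 kb merged, 15.5% of the H4K20me3 regions on H3K9me3 were kept. Seen from H3K9me3, the order was the other way. WT H3K9me3 peaks with H4K20me3 were kept in 79 of 1268 cases (6.23%, interval 4.96 to 7.70%) and those without in 373 of 13328 (2.80%, interval 2.53 to 3.09%). The 6.23% lay at percentile 99.6 of score-matched sets, whose mean was 4.77%, but these sets were not matched on length. From the shortest to the longest decile of length, the share of H3K9me3 peaks kept went from 1.37 to 12.1%. The share with H4K20me3 went from 2.47 to 27.7%, so this order was not separated from peak length.

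**Figure D3:**
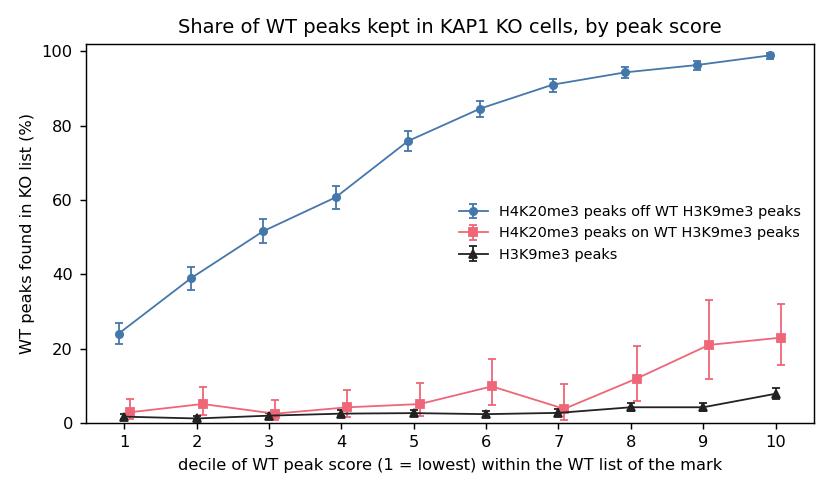
Share of WT peaks that overlap a KO peak of the same mark (vertical axis, %) by decile of WT peak score (horizontal axis), with exact 95% binomial intervals as bars. H4K20me3 peaks off H3K9me3 (blue circles) went from 24.0 to 98.9% across deciles, those on H3K9me3 (red squares) from 2.84 to 22.9%, and H3K9me3 peaks (black triangles) from 1.64 to 7.81%.

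Overlap of both marks was measured within each genotype, and the difference between genotypes was not tested. In WT, 1268 of 14596 H3K9me3 peaks overlapped an H4K20me3 peak (8.69%, interval 8.24 to 9.16%), which was 11.8 times the share under random placement. In KO, 103 of 3176 did (3.24%, interval 2.65 to 3.92%), or 4.98 times random placement. Among equal numbers of highest-scoring peaks the shares were 16.8% in WT and 3.24% in KO. With a score of at least 100 they were 11.5% in WT and 6.56% in KO. From the other side, 10.6% of WT H4K20me3 peaks and 1.15% of KO H4K20me3 peaks lay on H3K9me3 of the same genotype. The overlap in WT grew with the H3K9me3 score, from 2.53% in the lowest decile to 31.7% in the highest.

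The last comparison placed KAP1 peaks against the marks. In WT cells, 165 of 372 KAP1 peaks lay on H3K9me3 (44.4%, interval 39.2 to 49.6%) and 62 lay on H4K20me3 (16.7%). Random placement gave 0.684% and 0.653%. Both marks were present at 50 KAP1 peaks, H3K9me3 alone at 115, H4K20me3 alone at 12 and neither at 195. In the KO lists, 16 KAP1 positions lay on H3K9me3 (4.30%, interval 2.48 to 6.89%) and 16 on H4K20me3, and 343 lay on neither. Random placement gave 0.226% and 0.534% for the KO lists, so both overlaps still exceeded chance. The KO lists are also shorter than the WT lists, which lowers the overlap. With a score of at least 100, both KO shares were 1.16%, or 2 of 173. Of the 50 positions with both marks in WT, 41 had neither of those marks kept in KO.

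The highest-scoring KAP1 peaks all carried H3K9me3 in WT. The peak on chromosome 5 from 144014675 to 144017223 had a KAP1 score of 3100. It was followed by peaks on chromosome 8 (79972320 to 79973596, score 2931), chromosome 2 (157385094 to 157386547, score 2112), chromosome 6 (47974481 to 47975251, score 1600) and chromosome 10 (12810228 to 12811269, score 1596). All 5 overlapped a WT H3K9me3 peak, and the first 4 also a WT H4K20me3 peak. None of the 5 overlapped a peak of either mark in KO. In the highest decile of KAP1 score, 83.8% of the peaks lay on H3K9me3, and in the lowest 34.2%.

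**Figure D4:**
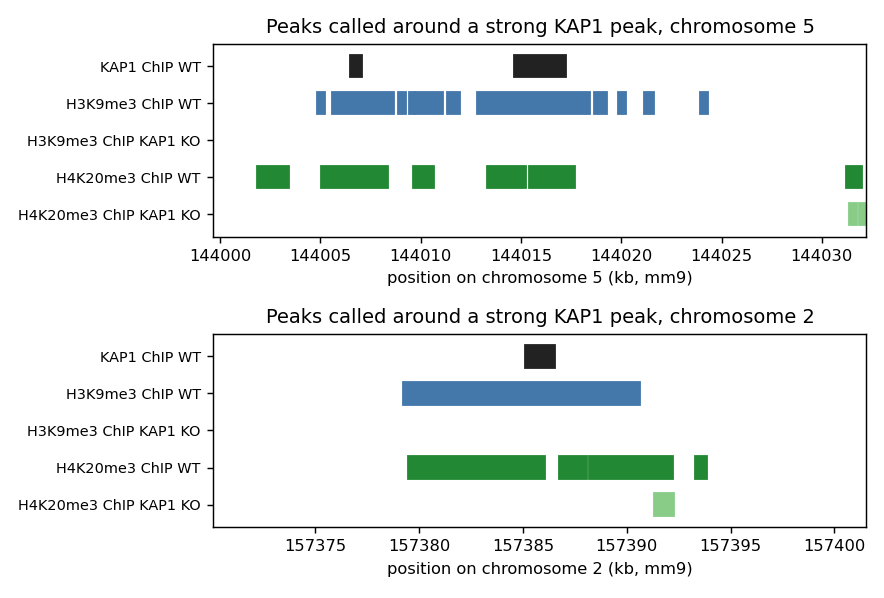
Maps of the peaks called in each of the 5 libraries (tracks) around KAP1 peaks on chromosome 5 and chromosome 2 (position in kb, mm9), where each block is a deposited peak drawn to scale. In both maps no H3K9me3 peak was called in KO, and the H4K20me3 peaks called in KO lay outside the KAP1 peaks.

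H3K9me3 loss was not limited to KAP1 peaks. Only 189 of the 14596 WT H3K9me3 peaks (1.29%) overlapped a KAP1 peak, and 13 of those 189 were kept (6.88%, interval 3.71 to 11.5%). Score-matched sets of H3K9me3 peaks kept 5.52% on average, and 6.88% lay at percentile 80.4 of these sets, so a difference at KAP1 sites was not detectable. With an overlap of at least 50% of the peak, 7 of 76 were kept, at percentile 99.4 of matched sets, and with a score of at least 100, 3 of 87 were (3.45%), at percentile 11.2. H4K20me3 peaks at KAP1 sites were kept less often than others of like score. Of 66, 17 were kept (25.8%, interval 15.8 to 38.0%), and no matched set kept less than 54.5%, with a mean of 73.8%. The share was 12.0% with an overlap of at least 50%, 7.89% with a score of at least 100 and 36.7% with peaks within 5 kb merged (22 of 60). The matched sets took no account of H3K9me3. Of those 66 peaks, 52 lay on H3K9me3 and 8 of the 52 were kept (15.4%, interval 6.88 to 28.1%), while 9 of the 14 away from H3K9me3 were kept. On H3K9me3 without a KAP1 peak, 82 of 1145 H4K20me3 peaks were kept (7.16%, interval 5.74 to 8.81%). Among peaks on H3K9me3, the share kept was thus not lower at KAP1 sites.

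Peak numbers differed between chromosomes in ways that the genotype label does not describe. For H4K20me3 the KO to WT ratio of peak numbers ranged from 0.549 on chromosome 13 to 1.45 on chromosome 18 and was below 1 on 17 of the 20 chromosomes. Over the 20 chromosomes, which are not independent replicates, the ratios of both marks had a Pearson r of 0.765 and a Spearman rho of 0.737. On chromosome 13 the numbers were 470 in WT and 258 in KO for H4K20me3, and 764 and 28 for H3K9me3. On chromosome 18 they were 170 and 247 for H4K20me3, and 146 and 62 for H3K9me3.

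**Figure D5:**
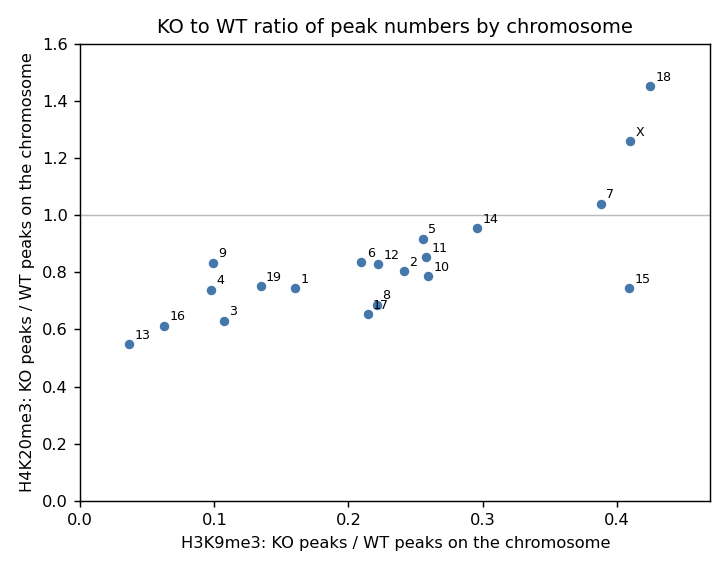
KO to WT ratio of peak numbers per chromosome (1 point per chromosome, 1 to 19 and X) for H3K9me3 (horizontal axis) and H4K20me3 (vertical axis), with a grey line at an H4K20me3 ratio of 1. Chromosome 13 was lowest for both marks, at 0.0366 and 0.549, and chromosome 18 was highest, at 0.425 and 1.45.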

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

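The tests of the H3K9me3 lists and of H4K20me3 peaks on H3K9me3 were chosen only after the results they measure, or tables that foreshadowed them, had been seen. For the tests over chromosomes, the peak numbers had been seen but the scores had not.

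On 3 chromosomes the marks went opposite ways between genotypes, with 1 library each, and the difference was not tested. The KO to WT ratio of H4K20me3 peak numbers was 1.04 on chromosome 7, 1.45 on chromosome 18 and 1.26 on chromosome X, while the H3K9me3 ratios there were 0.388, 0.425 and 0.410.

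The ratios of both marks varied together over the 20 chromosomes (Pearson r = 0.765, Spearman rho = 0.737, and r = 0.667 without chromosomes 18 and X; 3 relations were computed, and chromosomes are not independent replicates). The score ratio at 7307 H4K20me3 peaks shared by both genotypes and away from H3K9me3 had its lowest median on chromosome 13 (log2 of -0.60) and its highest on chromosome 18 (1.41), but X, high in both number ratios, had 0.02, with a median over chromosomes of 0.15. For this score ratio alone, regional differences of a few Mb unrelated to chromosome identity are argued against as the whole cause. Of its variance over 252 windows of 10 Mb, 66.0% lay between chromosomes, above all of 10000 permutations of the windows, whose mean was 7.57%. Windows were permuted independently, so differences over longer stretches of a chromosome stay open. The peak number ratios were not tested in this way, and a few Mb can weigh on them. Chromosome 15 held 890 WT and 364 KO H3K9me3 peaks, of which 9 and 114 lay at 87 to 88 Mb. A difference in copy number of whole chromosomes between the cultures is a candidate explanation, with a rho of 0.605 between the H3K9me3 number ratio and the H4K20me3 score ratio (0.643 without chromosomes 18 and X). It stays open because copy number was not measured here, and the 2 genotypes cannot be separated from the 2 cultures.

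The small overlap of the H3K9me3 lists may have several origins. A lower depth of the KO library as the only origin is argued against, because 58.2% of the 500 highest-scoring KO peaks, all with a score of at least 100, were absent from the larger WT list. These are KO peaks, so how many of the 14144 lost WT peaks depth could account for was not measured. A failed or low-yield KO precipitation without any change in the cells is argued against at peaks that also carry H4K20me3. A separate KO library kept 7.52% of the H4K20me3 peaks there, against 58.5% in score-matched sets. That library measured H4K20me3, so a failed H3K9me3 precipitation together with a change in H4K20me3 stays open at these peaks. At the 13328 WT peaks without H4K20me3, a failed precipitation cannot be told apart from a change in the cells. There 11.2% of KO peaks lay on such WT peaks, above the 1.73% maximum of random placements, but residual signal would give that too. The absence of KAP1 and any other difference between the cultures, such as repeats present in only 1 of them, also stay open and were not tested.

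H4K20me3 peaks on WT H3K9me3 were kept less often than others, and 3 technical explanations were tested. Weak peaks falling under the threshold are argued against as the whole cause, with 58.5% kept in sets matched on score. Peak length and chromosome are argued against likewise, with 64.4% and 63.8% kept in matched sets against 7.52% observed, which lay below every one of the 10000 sets in each case. Loss of KAP1 is the biological difference the design names, and it stays open as a hypothesis with differences between the cultures, since there was 1 library per genotype.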

How the results depend on the processing

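Of 136 values, 87 stayed and 49 moved, and the cause of a move was not tested unless named. To stay, a share had to lie within the interval of the reported value, and a count or ratio within 1.5 times it. A percentile had to stay on the same side of the middle 95% of matched sets. Shares were classed only as stayed or moved, so no reversal could be recorded for them. With equal numbers of peaks, the KAP1 list and both KO lists were unchanged by construction. The percentile of H3K9me3 kept at KAP1 sites stayed inside that range with a score of at least 100. The share as reported was above the matched mean (6.88 against 5.52%), and here it was below (3.45 against 6.52%). The 10 kb distance, the left-out windows and the class of H4K20me3 peaks on any WT H3K9me3 peak were added after the data were seen. Depth limits every value, since read numbers are unknown. No paired analysis was possible because each group held 1 library. The gene lists and gene contexts were not run, for want of an mm9 annotation.

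With an overlap of at least 50% of the peak, H3K9me3 WT peaks kept came to 2.56% and KO peaks absent in WT to 88.7%, H4K20me3 to 63.6% and 18.9%, KAP1 peaks with H3K9me3 in WT to 37.9%, H3K9me3 peaks with H4K20me3 to 6.77% in WT and 2.52% in KO, H4K20me3 kept on H3K9me3 to 5.41% and at KAP1 sites to 12.0%. H3K9me3 kept at KAP1 sites then lay at percentile 99.4 of matched sets, above their middle 95%, with 7 of 76 peaks kept. With a distance of up to 1 kb, H3K9me3 gave 3.95% kept and 83.3% absent, H4K20me3 67.9% and 13.8%, H3K9me3 with H4K20me3 11.6% in WT and 4.25% in KO, H4K20me3 kept where H3K9me3 was lost 7.15% and on any H3K9me3 9.93%. With a distance of up to 10 kb, H3K9me3 gave 6.59% kept and 72.3% absent.

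With a score of at least 100, counts were 173 for KAP1, 4593 and 549 for H3K9me3 in WT and KO. KO peaks absent in WT were 73.0% for H3K9me3 and 16.0% for H4K20me3, and 72.8% of H4K20me3 WT peaks were kept. KAP1 peaks with H3K9me3 in KO and with H4K20me3 in KO both came to 1.16%, peaks kept at KAP1 sites to 3.45% for H3K9me3 and 7.89% for H4K20me3, and H3K9me3 with H4K20me3 to 11.5% in WT and 6.56% in KO. With equal numbers of highest-scoring peaks, 3176 for H3K9me3, 5.95% were kept and 93.8% of KO peaks were absent from the shortened WT list. Shares absent could only rise here, because the WT lists were cut and the KO lists were not. The covered length ratio was 0.628 because the longer WT list was shortened. KAP1 peaks with H3K9me3 in WT were 32.8%, and H3K9me3 with H4K20me3 in WT 16.8%. H4K20me3 gave 75.6% kept, 23.4% absent from its shortened WT list and 9.67% kept on H3K9me3.

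With peaks within 5 kb merged, H4K20me3 gave 71.9% kept and 14.2% absent, 12.2% kept where H3K9me3 was lost and 15.5% on any H3K9me3, and 9.62% of H3K9me3 peaks met H4K20me3 in WT. On chromosomes 1 to 19 and X alone, H3K9me3 gave 2.52% kept and 88.4% absent. Without the 10 windows richest in KO peaks, 84.1% of H3K9me3 KO peaks were absent in WT.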

Other observations

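The windows with gains were chosen after their values were seen, and the test over chromosome X before. H3K9me3 peaks on sequences not placed on a chromosome in mm9 behaved apart from the rest. Of 213 such WT peaks, 90 were kept in KO (42.3%, interval 35.5 to 49.2%), and the KO list held 233, or 7.34% of its peaks against 1.46% in WT. On chromosomes 1 to 19 and X, 2.52% of WT H3K9me3 peaks were kept.

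H3K9me3 peaks were more numerous in KO in 231 windows of 1 Mb, of which the 3 with the largest gains are given here, and 2256 of the 2745 KO peaks absent in WT lay outside the 10 windows richest in KO peaks. On chromosome 15, the window from 87 to 88 Mb held 114 KO and 9 WT peaks, and the window from 86 to 87 Mb held 50 and 2. On chromosome 2, the window from 178 to 179 Mb held 39 and 2. These 3 windows held few H4K20me3 peaks in either genotype, between 0 and 3. The highest-scoring new H4K20me3 peaks in KO also lay together. On chromosome 6, peaks at 47108212 to 47111151 and 47089299 to 47092135 both had a score of 3100, and a peak at 47070824 to 47072807 had 1057, with no WT peak at any of them. The other 2 of the 5 highest lay on chromosome 13 (50907205 to 50909996, score 1261, and 50068855 to 50071300, score 847). The H4K20me3 window with the largest gain was 7 to 8 Mb of chromosome X, with 2 WT and 14 KO peaks.

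Strong H4K20me3 peaks in KO were almost free of WT H3K9me3. Of the 500 with the highest scores, 3 lay on a WT H3K9me3 peak (0.60%, interval 0.12 to 1.74%), while 57 of the 500 strongest WT H4K20me3 peaks did (11.4%, interval 8.75 to 14.5%).

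The WT H3K9me3 list held 3 peaks on chromosome Y and 25 on unplaced Y sequence, and the KO list held 1 and 0. A hypothesis that WT cells carry a Y and KO cells a second X was tested on the H4K20me3 score ratio of shared peaks, before those scores had been seen. The median log2 ratio on X was -0.10 relative to the autosomes (95% bootstrap interval -0.31 to 0.03, 118 peaks on X), short of the rise of at least 0.5 that was predicted. The test may not decide, because an inactive second X could carry few such peaks.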
